A study of Mus musculus with 9 samples.

How the data were processed

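Whole hearts of 9 mice were digested, stained for CD45 and sorted, per the labels' protocols, and libraries were made with the 10x Genomics 3' v3 chemistry and read on an Illumina NovaSeq. The deposited matrices hold raw UMI counts per gene and cell barcode, made by the submitters with bcl2fastq 2.20 and Cell Ranger 7.0.0 on mm10 (GRCm38), per the submitters' processing notes. The annotation release, the use of intronic reads, the use of strand in counting and any removal of free RNA are not given in the sources used here. The matrices list 32285 genes, of which 32235 matched gene IDs of GENCODE vM21, used for coordinates and transcript lengths. Xist and Y-linked UMIs matched the sex label in 9 of 9 libraries. The unit of the age label is not stated.

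Libraries held 48098 barcodes and 255244116 UMIs in all, with median UMIs per barcode from 2970 to 4479. Barcodes with at least 300 genes and under 15% mitochondrial UMIs were kept (45171; 2927 left out). Scrublet's own threshold marked only 12 of these (0.0266%) as doublets, so the 6% of cells with the highest score in each library were left out (2517 cells, 5.57%), a choice made after seeing the data. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, 30 principal components and 20 neighbours, Leiden clustering at resolution 1 with seed 0 gave 36 clusters. A cluster took the class with at least 3 fixed markers among its top 50 genes and 2 times the markers of the next class, with 20% detection required. Clusters without such a class stayed unnamed (5.39% of cells). The mixed cluster 13 among them held 0.159%, 0.346% and 22.9% of analysed cells in control mice 1 to 3. It held 0.258 ± 0.0899% in vehicle and 0.478 ± 0.407% in inhibitor mice. Class names describe marker patterns, and cells are called macrophage-like, T-like and so on for this reason.

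Counts were summed per library and class, for classes with at least 20 cells in every library. Macrophage-like cells numbered 230 to 858 per library, with 1023245 to 3677414 summed UMIs. Sums were tested with edgeR 4.0.16 (TMM, filterByExpr by group, quasi-likelihood fit and test with all 9 libraries and a mean per group, Benjamini-Hochberg adjustment, threshold 0.05). The contrasts were vehicle minus control, inhibitor minus vehicle and inhibitor minus control. Log2 fold changes carry a standard error derived from the F statistic. Fibroblast-like and endothelial-like cells did not reach 20 cells in every library and were tested as an addition after seeing the data. In data simulated from the inhibitor and vehicle libraries, with 200 genes changed, 42 of 52 genes changed by 2-fold and with a mean log2 CPM of at least 5 were called, and 9 of 9308 unchanged genes.

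Gene lists were tested with camera on voom values (limma 3.58.1) at a preset correlation of 0.01 and with the estimated correlation, adjusted over the lists of a class and contrast. In macrophage-like cells these were fibrogenic and lipid-associated, metalloproteinase, resident, monocyte-derived, MHC class I and II, type I interferon, interferon gamma, cytokine, profibrotic, glycolysis, sterol, lysosome, amino acid and ATF4, oxidative phosphorylation, cell cycle and dissociation lists, and marker lists of 14 other classes. T-like cells had effector and naive lists, neutrophil-like cells activation and maturity lists, fibroblast-like cells matrix, myofibroblast, resting, interferon and dissociation lists, and endothelial-like cells an activation list. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. In macrophage-like cells the rule names Tsc2, Itgax and Mmp12, up to 12 called genes with the largest rise and 12 with the largest fall among those with a mean log2 CPM of at least 5 whose groups do not overlap, and up to 4 members per list by smallest p. Chance separates 10% of genes in this way. Other classes had up to 4 genes per direction and 3 members per list. Symbols of predicted genes, clones and mitochondrial genes were left out of the largest changes.

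Shares of classes were taken among immune-like cells, since the sort sets the immune share, and compared by exact permutation over libraries, with 10 splits of 3 against 3 and 1680 assignments to 3 groups. Shares of macrophage-like cells with a UMI of 9 genes were taken after thinning every cell to 500 UMIs, with B-like and T-like cells as background. Groups with 0 counts of a gene are given as bounds from a floor of 3 counts over the group, and with 1 to 3 counts as ratios with 95% counting intervals. The overlap of the contrasts that share controls was set against 20 simulated data sets without effect. Alternatives were DESeq2's size factors and its Wald test (version 1.42.0), no low-count filter, fits of the 2 groups compared, sex or age as covariate, each replicate left out, doublets kept, at least 500 genes and under 8% mitochondrial UMIs, resolutions 0.5 and 2, a 2-fold minimum and markers of other classes left out. Alternatives added after seeing the data were the macrophage-like cells without the Gpnmb-led cluster, with the mixed low-UMI cluster, of at least 2000 UMIs or with a lowess trend (span 0.3) on transcript length removed, T-like cells without the Lef1-led clusters, and both Cre-positive groups against control (84 splits). Other tools were Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and R 4.3.3.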

Results

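Single-cell RNA sequencing was run on digested whole mouse hearts. Cells were sorted for CD45, the surface protein of leukocytes, with some CD45-negative cells kept. Per the labels, 9 hearts fell into 3 groups of 3 mice. Control mice carried floxed Tsc2 alleles with no Cre in the label. The vehicle and inhibitor groups carried the same alleles with a CD11c Cre transgene, and their phenotype label is sarcoidosis, a disease with granulomas. Vehicle mice were gavaged with the solvent and inhibitor mice with Linvemastat, an inhibitor of MMP12, the macrophage elastase. Tsc2 encodes tuberin, a brake on the growth kinase complex mTORC1, and CD11c is the integrin encoded by Itgax. The series title names cardiac fibrosis. Each group held 2 females and 1 male.

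The libraries held 4682 to 6203 cell barcodes. Total unique molecular identifiers (UMIs, each standing for a captured transcript) were 34673728, 26815073 and 25321179 in control mice 1 to 3. They were 32476503, 25546687 and 24298502 in vehicle mice and 28577693, 32174555 and 25360196 in inhibitor mice. Of 42654 analysed cells, 38693 fell in clusters named as immune classes, 1661 in non-immune classes and 2300 in unnamed clusters. Control mouse 3 had 24.9% of its cells in unnamed clusters, against 1.63% to 3.95% in the other libraries. Replicates are separate mice. P-values of edgeR and of permutations measure only the spread between these mice. Those of camera also rest on the correlation set between genes, and counting intervals pool UMIs over mice.

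In summed counts of macrophage-like cells, Tsc2 (ENSMUSG00000002496, GRCm38 chromosome 17, 24595816 to 24632630) stood at 10.6, 14.7 and 11.8 CPM (counts per library scaled to the same total) in the control mice. It stood at 7.74, 2.75 and 8.05 in the vehicle mice and at 7.97, 6.15 and 6.54 in the inhibitor mice. The log2 fold change was −1.03 ± 0.38, adjusted p = 0.0607 (SE, n = 3 per group) for vehicle minus control and −0.84 ± 0.34, adjusted p = 0.0955 for inhibitor minus control, and neither passed the test. These 3' tags read the end of the transcript, and the floxed exons are not given in the sources used here, so this level checks neither the deletion nor the labels.

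The vehicle against control comparison asks what macrophages of Cre-positive hearts express. Their macrophage-like cells carried far more transcript of Gpnmb, Spp1, Fabp5 and Lgals3 than those of control hearts. Gpnmb, a membrane glycoprotein of lipid-laden macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), stood at 2282 ± 311 CPM in vehicle mice and 2.67 ± 2.27 in control mice (mean ± SD, n = 3). Spp1, the secreted matrix protein osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), stood at 1402 ± 303 against 13.1 ± 8.05 CPM. Fabp5, a fatty acid carrier, stood at 7162 ± 853 against 47.3 ± 30.5 CPM, and the lectin Lgals3 (galectin-3) at 9645 ± 1819 against 328 ± 31.9. Retnla, a secreted protein of alternatively activated macrophages, lay lower (75.3 ± 42.8 against 917 ± 638 CPM).

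By edgeR's quasi-likelihood test, 1609 of 9877 genes rose and 1194 fell at an adjusted p under 0.05 in this comparison, 819 and 315 of them by at least 2-fold. The log2 fold changes were 9.39 ± 0.45, adjusted p = 2.30e-07 for Gpnmb, 6.62 ± 0.44, adjusted p = 2.87e-06 for Spp1, 7.26 ± 0.53, adjusted p = 5.09e-06 for Fabp5 and 4.88 ± 0.21, adjusted p = 2.08e-07 for Lgals3. Other large rises were those of Ctsk, a collagen-degrading protease (9.47 ± 0.57), Syngr1 (7.62 ± 0.44), Hal, a histidine-degrading enzyme (7.26 ± 0.53), Atp6v0d2, a proton pump subunit (6.80 ± 0.47), Mfge8, a bridge to apoptotic cells (6.26 ± 0.29), and Ccdc148 (5.97 ± 0.59). Control libraries held 1 count of Bex1 and 1 of the protease Htra1, giving ratios of 4768 (95% counting interval 855.1 to 188376) and 301 (53.3 to 11933). Tceal7 had 0 control counts and was at least 129-fold higher against a floor of 3 counts over the group.

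The largest falls were those of Retnla (−3.60 ± 0.71, adjusted p = 0.00312), the collagenase Mmp13 (−2.37 ± 0.42), the lectin Cd207 (−1.96 ± 0.55), Plekhg5 (−1.92 ± 0.44), Adgre4 (−1.85 ± 0.33) and Fcrls (−1.77 ± 0.45). Vsig4, a complement receptor (−1.72 ± 0.36), Rhobtb1 (−1.52 ± 0.31), the mTOR-binding protein gene Deptor (−1.46 ± 0.27), Mctp1 (−1.46 ± 0.24), the lectin Mgl2 (−1.45 ± 0.22) and the collagen-modifying P3h2 (−1.45 ± 0.20) also fell. Itgax did not pass the test (0.39 ± 0.49, adjusted p = 0.586), and neither did Mmp12 (0.97 ± 0.37, adjusted p = 0.0680), which stood at 109 ± 16.0 against 56.0 ± 28.0 CPM.

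**Figure D1:**
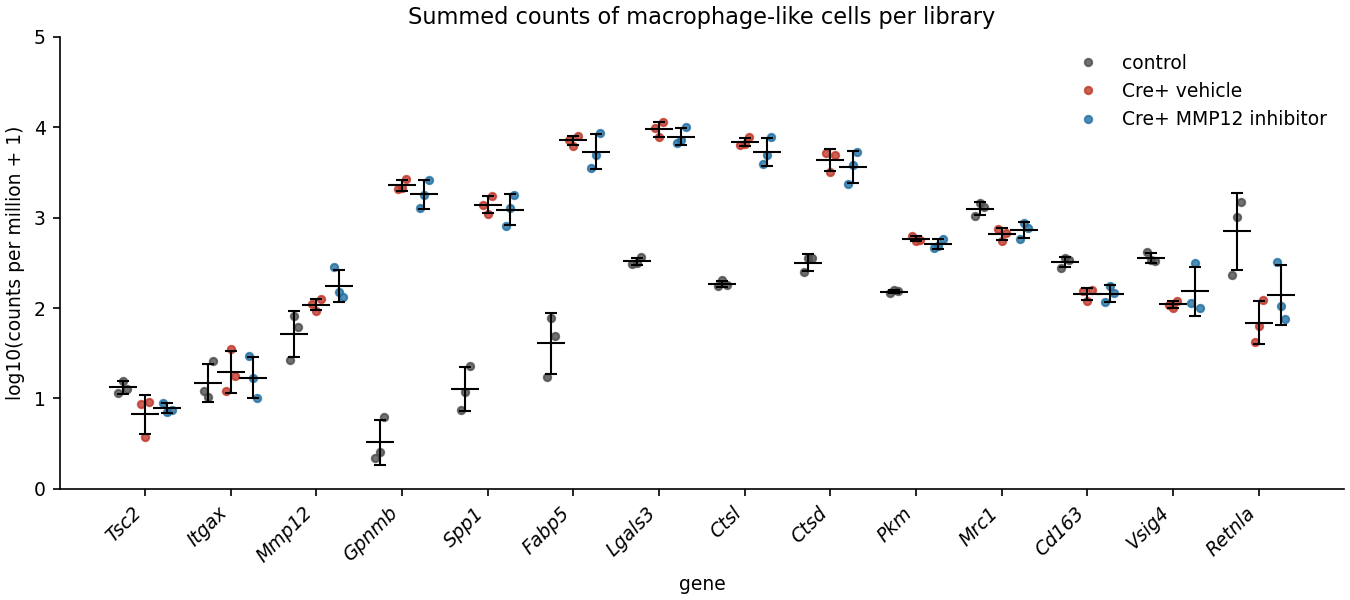
CPM of 14 genes in summed counts of macrophage-like cells, on a log10(CPM + 1) axis, for control, vehicle and inhibitor mice. Points are libraries and black bars the mean ± SD of 3 mice. Gpnmb lies at 2.67 CPM on average in control mice and 2282 in vehicle mice.

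Of the list of fibrogenic and lipid-associated macrophages, 22 of 28 measured members rose and 0 fell (23 and 0 adjusted over the list alone), with Ctsl, a lysosomal protease, at 5.22 ± 0.25 (median 2.44, camera adjusted p = 1.33e-19, adjusted p = 0.179 with an estimated correlation). Of the lysosome list, 27 of 42 measured members rose and 1 fell (28 and 1 adjusted over the list alone), among them the protease genes Ctsd (3.78 ± 0.30) and Ctsb (1.91 ± 0.18) (median 0.72, camera adjusted p = 1.56e-11, adjusted p = 0.384 with an estimated correlation). Of metalloproteinases and their inhibitors, 5 of 12 measured members rose and 2 fell (6 and 3 adjusted over the list alone). Adam8 (2.83 ± 0.27) and the inhibitor Timp2 (1.71 ± 0.22) rose, Mmp27 had 0 control counts and was at least 48.5-fold higher, and the list as a whole was not called (median 0.53, also with Mmp27 at its bound, adjusted p = 0.326). Of profibrotic factors, 5 of 15 measured members rose and 2 fell (5 and 2 adjusted over the list alone), with rises of Tnfsf12, the cytokine TWEAK (1.02 ± 0.17), and Grn, progranulin (1.04 ± 0.18), and no call for the list (adjusted p = 0.204).

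In the list of resident macrophages, 1 of 26 measured members rose and 10 fell (1 and 16 adjusted over the list alone) (median −0.92, camera adjusted p = 1.22e-04, adjusted p = 0.722 with an estimated correlation). Cd163, the haemoglobin scavenger receptor (−1.18 ± 0.19), the prostaglandin-degrading Hpgd (−1.29 ± 0.22) and the mannose receptor Mrc1 (−0.94 ± 0.19) fell, while Selenop, a selenium carrier, rose (1.98 ± 0.33). Of monocyte-derived genes, 3 of 17 measured members rose and 0 fell (1 and 0 adjusted over the list alone), namely lysozyme Lyz2 (0.84 ± 0.18), Chil3 (1.95 ± 0.64) and Ms4a4c (0.96 ± 0.33), and the list was not called (adjusted p = 0.787). MHC class II had 0 called members of 10 by edgeR over all genes and over the list alone, with Cd74 at −0.65 ± 0.29, adjusted p = 0.115, and no call (camera adjusted p = 0.0768). Of MHC class I genes, 4 of 15 measured members rose and 0 fell (5 and 0 adjusted over the list alone), with H2-T22 (1.11 ± 0.21), H2-D1 (0.72 ± 0.15), H2-T23 (0.71 ± 0.23) and the immunoproteasome gene Psmb8 (0.65 ± 0.23) up and no call for the list (adjusted p = 0.204).

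Of the type I interferon response, 0 of 26 measured members rose and 1 fell (0 and 0 adjusted over the list alone), with the RNA sensor Oas2 at −0.74 ± 0.23, adjusted p = 0.0299 and Irf7 at 0.74 ± 0.26, adjusted p = 0.0512, and no call for the list (adjusted p = 0.787). Of the interferon gamma response, 2 of 17 measured members rose and 0 fell (1 and 0 adjusted over the list alone), namely the antibody receptor Fcgr4 (1.04 ± 0.26) and the T-cell chemokine Cxcl9 (5.45 ± 1.81), and the list was not called (adjusted p = 0.519). Of cytokines and NF-kB targets, 2 of 22 measured members rose and 2 fell (2 and 2 adjusted over the list alone). The chemokines Ccl8 (3.04 ± 0.38) and Cxcl16 (0.61 ± 0.16) rose and Tnf (−1.11 ± 0.22) and Nfkbiz (−0.98 ± 0.23) fell (adjusted p = 0.476, not called).

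Of oxidative phosphorylation genes, 40 of 43 measured members rose and 0 fell (42 and 0 adjusted over the list alone), for example Ndufa1 (2.83 ± 0.27), Cox5a (1.90 ± 0.21), Uqcrq (1.68 ± 0.16) and cytochrome c, Cycs (1.30 ± 0.13) (median 1.09, camera adjusted p = 2.48e-23, adjusted p = 0.307 with an estimated correlation). Of glycolysis genes, 7 of 15 measured members rose and 0 fell (7 and 0 adjusted over the list alone), with Pkm (1.94 ± 0.15), Pgam1 (1.94 ± 0.15), Pgk1 (2.07 ± 0.18) and Ldha (1.65 ± 0.14) up (median 0.46, camera adjusted p = 1.22e-04, adjusted p = 0.115 with an estimated correlation). Of sterol synthesis genes, 8 of 19 measured members rose and 0 fell (9 and 0 adjusted over the list alone), with Mvd (2.54 ± 0.30), Fdps (2.57 ± 0.31), Hmgcs1 (1.53 ± 0.19) and Pmvk (1.35 ± 0.28) up (median 0.78, camera adjusted p = 0.00439, adjusted p = 0.384 with an estimated correlation). Of amino acid and ATF4 genes, 3 of 20 measured members rose and 0 fell (3 and 0 adjusted over the list alone), namely Atf5 (2.33 ± 0.36), the stress cytokine Gdf15 (2.93 ± 0.46) and Sars (1.02 ± 0.18), with no call for the list (adjusted p = 0.476).

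Of cell cycle genes, 0 of 22 measured members rose and 2 fell (0 and 2 adjusted over the list alone), namely Mcm5 (−1.64 ± 0.34) and Rrm1 (−1.44 ± 0.40), and the list was not called (adjusted p = 0.204). Of genes induced by tissue dissociation, 0 of 23 measured members rose and 7 fell (0 and 11 adjusted over the list alone), among them Btg2 (−0.79 ± 0.16), Egr1 (−1.14 ± 0.25), Ier2 (−0.92 ± 0.20) and Fosb (−1.13 ± 0.27) (median −0.79, camera adjusted p = 7.21e-04, adjusted p = 0.722 with an estimated correlation). Among marker lists of 14 other cell classes, the cardiomyocyte list fell, with 5 of 11 members called down (7 adjusted over the list alone, median −1.34, camera adjusted p = 0.00965, adjusted p = 0.269 with an estimated correlation). The other 13 were not called, with camera adjusted p from 0.149 for conventional dendritic cells (cDC) to 0.843 for endothelial cells, and median and test had opposite signs for pDC, B-cell, endothelial and platelet markers.

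Several measured facts stand beside all of these gene groups. Most macrophage-like cells of Cre-positive mice lay in cluster 3, led by Gpnmb, which held 0, 0 and 4 cells of control mice 1 to 3, and most of those of control mice in cluster 8, led by Mrc1 and Cd163, and the low-UMI cluster 25. Median UMIs per macrophage-like cell were 4433 in control, 1535 in vehicle and 1607 in inhibitor mice, and 1260 in cluster 3 against 5787.5 in cluster 8. The median mitochondrial share of UMIs was 0.598% in cluster 3 and 2.74% in cluster 8. In macrophage-like cells it was 2.98% to 3.55% in control, 0.746% to 2.71% in vehicle and 0.909% to 1.20% in inhibitor libraries. Fold changes followed transcript length, with a Spearman correlation across genes, which are not independent replicates, of −0.391. With genes in 5 equal groups by length, 36.9% of the shortest (66 to 1886 nt) rose and 3.90% fell, and of the longest (5280 to 123179 nt) 3.90% rose and 26.8% fell.

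Settings chosen after seeing the data moved these calls. Without the Gpnmb-led cluster edgeR called 0 genes (749 at an unadjusted p under 0.05), and 7 of the 66 named genes that were called and still measured changed sign, Timp2, Selenop, Tnfsf12, Fdps, Ctsb, Atf5 and Gdf15. With each library's trend on transcript length removed, 1272 genes rose and 737 fell, and the oxidative phosphorylation median was 0.71. There MHC class II was called lower, with 3 of 10 members down (5 adjusted over the list alone, median −0.78, camera adjusted p = 0.00280, adjusted p = 0.509 with an estimated correlation). So were cytokines, with 2 members up and 6 down (2 and 10 adjusted over the list alone, median −0.66, camera adjusted p = 0.0322, adjusted p = 0.556 with an estimated correlation). Cell cycle genes were called lower, with 1 down (1 adjusted over the list alone, median −0.54, camera adjusted p = 0.0322, adjusted p = 0.691 with an estimated correlation).

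Without the Gpnmb-led cluster list calls stayed, ended or came in, with 0 members called over all genes. Calls that stayed were those of resident macrophage (median −0.44, camera adjusted p = 2.53e-09) and fibrogenic genes (0.47, camera adjusted p = 3.97e-07). Oxidative phosphorylation (0.19, camera adjusted p = 1.55e-07) and glycolysis genes (0.36, camera adjusted p = 0.00222) also stayed called. So did dissociation (−0.28, camera adjusted p = 0.00250) and cardiomyocyte marker lists (−1.14, camera adjusted p = 8.84e-06). In this order, adjusted p with an estimated correlation was 0.563, 0.233, 0.606, 0.563, 0.795 and 0.0731. Calls not seen with the cluster were those of monocyte-derived (0.65, camera adjusted p = 3.17e-07, adjusted p = 0.488 with an estimated correlation), MHC class I (0.36, camera adjusted p = 0.00116, adjusted p = 0.760 with an estimated correlation) and interferon gamma genes (0.82, camera adjusted p = 0.00397, adjusted p = 0.811 with an estimated correlation), higher. Cell cycle genes were newly called lower (−0.69, camera adjusted p = 0.00177, adjusted p = 0.563 with an estimated correlation). The sterol synthesis median was −0.0704 (camera adjusted p = 0.384) and lysosome genes were not called (adjusted p = 0.829).

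**Figure D2:**
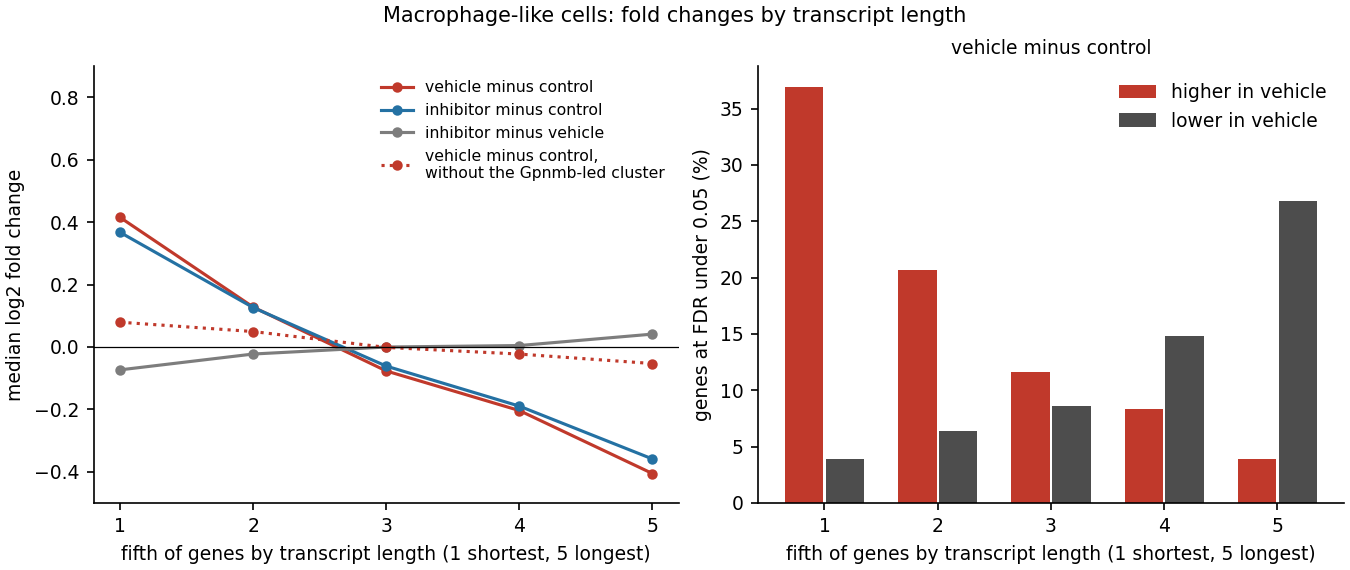
Left, median log2 fold change of genes in 5 equal groups by transcript length in macrophage-like cells, for 3 contrasts and, dotted, for vehicle minus control without the Gpnmb-led cluster. Right, percent of genes called up or down for vehicle minus control in each group, falling from 36.9% to 3.90% for rises.

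Single cells were also scored for the presence of each transcript. After thinning every macrophage-like cell to 500 UMIs (1179 control, 1180 vehicle and 2007 inhibitor cells, 0 left out), 0.0973 ± 0.169% of control, 38.9 ± 2.90% of vehicle and 34.9 ± 6.26% of inhibitor cells held a Gpnmb UMI (mean ± SD, n = 3 mice). For Spp1 the shares were 0.467 ± 0.517% of control, 30.1 ± 6.45% of vehicle and 30.2 ± 6.06% of inhibitor cells. The lipid receptor gene Trem2 was detected in 8.98 ± 2.68% of control, 26.6 ± 4.31% of vehicle and 29.8 ± 3.98% of inhibitor cells and Mmp12 in 1.78 ± 0.787% of control, 5.49 ± 0.561% of vehicle and 5.87 ± 1.58% of inhibitor cells. Lyve1 and Timd4, markers of long-lived resident macrophages, were detected in 12.2 ± 2.30% of control, 2.56 ± 0.140% of vehicle and 2.24 ± 2.21% of inhibitor cells and in 5.10 ± 1.16% of control, 0.755 ± 0.659% of vehicle and 1.89 ± 0.478% of inhibitor cells. Unthinned shares in control, vehicle and inhibitor mice were 0.708%, 52.3% and 49.0% for Gpnmb, 2.38%, 45.0% and 43.9% for Spp1, 45.6%, 58.5% and 58.7% for Trem2, 5.41%, 11.9% and 12.2% for Mmp12, 35.3%, 7.94% and 8.01% for Lyve1 and 25.9%, 6.37% and 8.52% for Timd4.

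Thinned shares of the chemokine receptor gene Ccr2 were 8.38%, 3.59% and 2.36%, of Itgax 0.486%, 0.327% and 0.496% and of Arg1 0.0487%, 0.0969% and 0.454%. In B-like cells, which should lack Gpnmb, the thinned shares were 0%, 0.292% and 0.638% for Gpnmb and 0%, 0.244% and 0.386% for Spp1, at median depths of 3498, 3749 and 3128 UMIs. B-like cells with an Mmp12 UMI made up 0.0129%, 0% and 0.0641%. A share of 0% has an upper limit of 0.0557% in control and 0.0683% in vehicle B-like cells, from a floor of 3 cells over the group. In T-like cells Gpnmb shares were 0% (limit 0.101%), 0.530% and 0.896% and Ccr2 shares 4.07%, 8.72% and 11.2%, at median depths of 5397, 4905 and 4745 UMIs. Pairwise exact permutation tests of 3 against 3 mice cannot go below p = 0.1, which vehicle against control gave for Gpnmb, Spp1, Trem2, Mmp12, Lyve1 and Timd4. Over the 3 groups the exact permutation p adjusted over 9 genes was 0.0429 for Gpnmb, Trem2 and Timd4, 0.0536 for Spp1, Mmp12 and Lyve1 and 0.0735 for Ccr2. Inhibitor against vehicle gave exact p = 0.400 for Gpnmb, 1 for Spp1, 0.400 for Trem2 and 0.9 for Mmp12. These are shares of cells sorted on CD45, the thinned ones at equal depth.

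**Figure D3:**
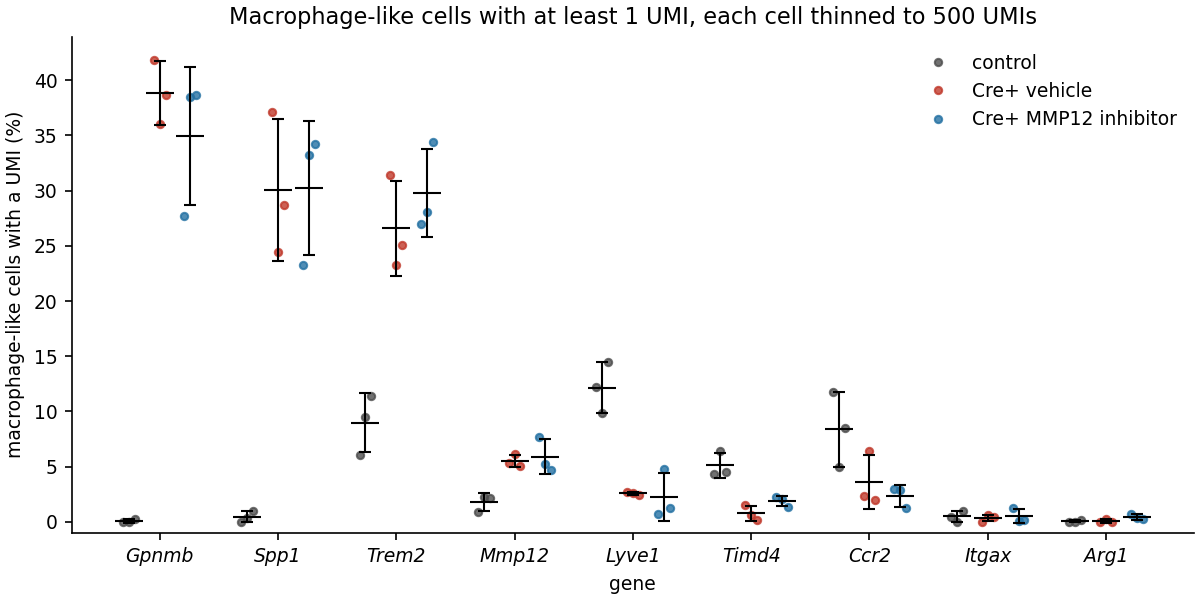
Percent of macrophage-like cells with at least 1 UMI of each of 9 genes after thinning to 500 UMIs, by group. Points are libraries and black bars the mean ± SD of 3 mice. Gpnmb was detected in 0.0973% of control and 38.9% of vehicle cells on average.

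The inhibitor against vehicle comparison asks what MMP12 inhibition changed in Cre-positive hearts. In macrophage-like cells of inhibitor mice Gpnmb stood at 1894 ± 693 CPM, against 2282 ± 311 in vehicle mice, and Lgals3 differed by −0.27 ± 0.18 on the log2 scale. Mmp12 itself stood at 187 ± 81.9 CPM in inhibitor and 109 ± 16.0 in vehicle mice (0.77 ± 0.35). The matrix protein fibronectin, Fn1, stood at 60.3 ± 46.8 against 269 ± 165 CPM (−2.12 ± 0.55). The chemokine Ccl4 (1.22 ± 0.35) and Tnf (0.66 ± 0.22) lay higher on average and the monocyte genes Chil3 (−1.62 ± 0.62) and Ccr2 (−0.84 ± 0.32) lower, none past the test.

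By edgeR 0 of 9877 genes were called, with 340 at an unadjusted p under 0.05, and DESeq2 called 0. In simulated data of this comparison edgeR called 54 of 97 genes changed by 2-fold and 93 of 97 changed by 4-fold, among 9502 genes. Without the low-count filter 104 genes were called, 61 up and 43 down.

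No list had a member called over all genes. Camera called 11 lists, whose calls were all lost with an estimated correlation. Oxidative phosphorylation (−0.17, adjusted p = 6.67e-08) and fibrogenic genes (−0.21, adjusted p = 0.00300) had negative medians. So had monocyte-derived genes (−0.46, adjusted p = 0.0269) and glycolysis (−0.09, adjusted p = 0.0420). In this order, adjusted p with an estimated correlation was 0.713, 0.713, 0.713 and 0.631. Positive medians were found for cell cycle genes (0.69, adjusted p = 0.0197) and MHC class I (0.19, adjusted p = 0.0258). Amino acid and ATF4 genes also had one (0.18, adjusted p = 0.0258). Markers of NK cells (2.64, adjusted p = 3.57e-04) and T cells (0.41, adjusted p = 0.00300) also had positive medians. So had those of neutrophils (0.36, adjusted p = 0.00300) and cardiomyocytes (0.57, adjusted p = 0.00300). In this order, adjusted p with an estimated correlation was 0.713, 0.737, 0.673, 0.673, 0.713, 0.673 and 0.460. Adjusted over the list alone, 4 of 9 NK and 3 of 11 cardiomyocyte markers were higher and 1 of 15 profibrotic factors lower. Without inhibitor mouse 1 the MHC class I median was −0.16, without vehicle mouse 2 the monocyte-derived median was 0.09, and with doublets kept, where camera called 5 lists, the T-cell marker median was −0.27 and the ATF4 median 0.0366. Without the Gpnmb-led cluster camera called 8 lists. The fibrogenic median was then 0.0279 (adjusted p = 0.481) and the cell cycle median −0.0758 (adjusted p = 0.818). Glycolysis and T-cell markers were not called there. Cytokines were (median 0.27, adjusted p = 0.00510, adjusted p = 0.673 with an estimated correlation). With the trend on transcript length removed cytokines were also called (median 0.29, adjusted p = 0.0190, adjusted p = 0.657 with an estimated correlation), and monocyte-derived genes were not (adjusted p = 0.0515).

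The remaining lists were not called in this comparison. Camera adjusted p was 0.721 for metalloproteinases (Mmp19 −1.08 ± 0.45), 0.964 for resident macrophage genes (Vsig4 0.69 ± 0.35), 0.134 for MHC class II, 0.204 for the type I interferon response (Oas3 −1.13 ± 0.35) and 0.856 for the interferon gamma response. It was 0.0556 for cytokines (Ccl3 0.76 ± 0.26), 0.129 for profibrotic factors (Thbs1 −1.09 ± 0.42), 0.573 for sterol synthesis, 0.0922 for lysosome genes (Sqstm1 0.52 ± 0.17) and 0.490 for dissociation genes.

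The inhibitor against control comparison asks what remained different in Cre-positive hearts under the inhibitor. The leading genes of the vehicle comparison were again far higher, with Gpnmb at 1894 ± 693 CPM against 2.67 ± 2.27 in control mice and Spp1 at 1293 ± 496 against 13.1 ± 8.05. Mmp12 rose here (1.74 ± 0.36, adjusted p = 0.00541), at 187 ± 81.9 against 56.0 ± 28.0 CPM. Fn1 fell (−1.70 ± 0.54, adjusted p = 0.0414). Itgax did not pass (0.09 ± 0.47, adjusted p = 0.912).

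By edgeR 1384 of 9877 genes rose and 844 fell, 616 and 166 of them by at least 2-fold. Rises included Gpnmb (9.12 ± 0.45), Ctsk (9.04 ± 0.57), Syngr1 (7.41 ± 0.44), Fabp5 (6.93 ± 0.52), Hal (6.69 ± 0.53), Spp1 (6.50 ± 0.44), Atp6v0d2 (6.37 ± 0.47), Mfge8 (5.56 ± 0.29) and Cxcl9 (5.47 ± 1.80). Bex1 and Htra1, with 1 control count each, gave ratios of 3187 (95% counting interval 572 to 125911) and 265 (47.1 to 10495), and Tceal7 and Mmp27 were at least 72.6-fold and 41.5-fold higher. Falls included Cd209f (−2.52 ± 0.72), Plekhg5 (−2.0 ± 0.41), Mmp13 (−1.79 ± 0.37), the eotaxin gene Ccl24 (−1.65 ± 0.42), Rhobtb1 (−1.48 ± 0.29), Satb1 (−1.47 ± 0.29), cyclooxygenase-1, Ptgs1 (−1.45 ± 0.33), Fcrls (−1.35 ± 0.43), Plxna4 (−1.34 ± 0.30), Lyz1 (−1.33 ± 0.30) and Deptor (−1.28 ± 0.25).

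By list, fibrogenic genes had 23 up and 1 down of 28 (23 and 1 adjusted over the list alone, median 2.35, camera adjusted p = 4.48e-20, adjusted p = 0.174 with an estimated correlation), with Ctsl at 4.90 ± 0.25 and Lgals3 at 4.61 ± 0.21. Lysosome genes had 26 up and 1 down of 42 (28 and 1 adjusted over the list alone, median 0.68, camera adjusted p = 3.73e-12, adjusted p = 0.353 with an estimated correlation), with Ctsd at 3.57 ± 0.30. Oxidative phosphorylation genes had 37 up and 0 down of 43 (39 and 0 adjusted over the list alone, median 0.92, camera adjusted p = 5.02e-21, adjusted p = 0.353 with an estimated correlation), with Ndufa1 at 2.26 ± 0.27. Glycolysis genes had 6 up and 0 down of 15 (7 and 0 adjusted over the list alone, median 0.47, camera adjusted p = 6.24e-04, adjusted p = 0.174 with an estimated correlation), with Pgam1 at 1.89 ± 0.15 and Pkm at 1.75 ± 0.15. Sterol synthesis genes had 9 up and 1 down of 19 (11 and 1 adjusted over the list alone, median 0.86, camera adjusted p = 0.00172, adjusted p = 0.353 with an estimated correlation), with Fdps at 2.58 ± 0.30 and Msmo1 at 1.23 ± 0.23. Resident macrophage genes had 1 up and 13 down of 26 (1 and 16 adjusted over the list alone, median −0.89, camera adjusted p = 1.73e-05, adjusted p = 0.662 with an estimated correlation), with Cd163 at −1.14 ± 0.18 and Stab1 at −0.96 ± 0.22. MHC class I genes had 3 up and 0 down of 15 (5 and 0 adjusted over the list alone, median 0.53, camera adjusted p = 0.00875, adjusted p = 0.738 with an estimated correlation), with H2-T22 at 1.13 ± 0.21. Dissociation genes had 0 up and 7 down of 23 (0 and 10 adjusted over the list alone, median −0.68, camera adjusted p = 6.78e-04, adjusted p = 0.662 with an estimated correlation), with Egr1 at −0.95 ± 0.25.

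Lists not called against control were metalloproteinases, 5 up and 2 down of 12 (5 and 3 adjusted over the list alone, camera adjusted p = 0.402), with Mmp14 at 2.21 ± 0.41, and amino acid and ATF4 genes, 6 up and 0 down of 20 (6 and 0 adjusted over the list alone, camera adjusted p = 0.0638), with Gdf15 at 3.45 ± 0.45 and Mthfd2 at 0.81 ± 0.23. Profibrotic factors had 5 up and 2 down of 15 (5 and 3 adjusted over the list alone, camera adjusted p = 0.474), a median of −0.22 and a mean of 0.58, with Pdgfa at 1.52 ± 0.23. Cytokines had 3 up and 1 down of 22 (3 and 1 adjusted over the list alone, camera adjusted p = 0.926), with Ccl8 at 2.55 ± 0.38, Ccl5 at 1.83 ± 0.51 and Ccl9 at −0.73 ± 0.22. The interferon gamma response had 2 up and 0 down of 17 (1 and 0 adjusted over the list alone, camera adjusted p = 0.402), the type I interferon response 0 up and 1 down of 26 (0 and 0 adjusted over the list alone, camera adjusted p = 0.926), monocyte-derived genes 1 up and 0 down of 17 (0 and 0 adjusted over the list alone, camera adjusted p = 0.698), MHC class II 0 up and 0 down of 10 (0 and 0 adjusted over the list alone, camera adjusted p = 0.192) and cell cycle genes 0 up and 1 down of 22 (0 and 0 adjusted over the list alone, camera adjusted p = 0.568). Median and test had opposite signs for cell cycle (median 0.26), type I interferon (0.09) and profibrotic genes, and the cytokine median was −0.17 with a mean of 0.04. The marker lists of 14 other classes were not called, the cardiomyocyte list at adjusted p = 0.0664 and the NK list at 0.0793.

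Both contrasts share the control libraries. The same 1268 genes rose and 659 fell in both contrasts, 0 in opposite directions, where independent lists would share 225 and 102. In 20 simulated data sets without effect the shared calls averaged 0.25 and reached 3. Fold changes correlated across genes at 0.919 (simulated 0.474), with covariance 0.637 against a simulated 0.0481, a difference of 0.589. The controls are too few to split, and part of the excess over these values can come from the shared controls. Without control mouse 1 inhibitor minus control called 1459 genes, without inhibitor mouse 3 it called 1357, and without the Gpnmb-led cluster 0 (574 at an unadjusted p under 0.05) by edgeR. Without that cluster Mmp12, Timp2, Selenop, Lyz2, Tnfsf12, Msmo1 and Atf5 changed sign, Mmp12 to −0.0279 from 1.74, among 64 named called genes still measured. There glycolysis (adjusted p = 0.0682), sterol synthesis (adjusted p = 0.906) and lysosome genes (adjusted p = 0.130) were not called by camera. Lists called higher there and not with the cluster were monocyte-derived (median 0.29, adjusted p = 0.0285) and type I interferon genes (0.14, adjusted p = 0.0285). So were interferon gamma (1.36, adjusted p = 1.48e-04) and ATF4 genes (0.11, adjusted p = 0.00597). Markers of T cells (0.74, adjusted p = 6.30e-04) and NK cells (1.46, adjusted p = 1.86e-04) were likewise called higher. Cell cycle genes were called lower (−0.48, adjusted p = 1.32e-05). In this order, adjusted p with an estimated correlation was 0.614, 0.323, 0.614, 0.298, 0.614, 0.323 and 0.323. With the trend on transcript length removed MHC class II (−0.60, adjusted p = 0.0164, adjusted p = 0.663 with an estimated correlation) and cardiomyocyte markers (−1.07, adjusted p = 0.00133, adjusted p = 0.270 with an estimated correlation) were called lower.

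T-like cells of Cre-positive hearts carried less transcript of naive genes and more of effector genes than those of control hearts. Gzmk, a granzyme of effector T cells (chromosome 13, 113171608 to 113225908), stood at 205 ± 74.8 CPM in vehicle and 17.0 ± 10.7 in control mice (3.61 ± 0.49, adjusted p = 0.0329). Lef1, a transcription factor of naive T cells, stood at 187 ± 31.6 against 845 ± 314 CPM (−2.17 ± 0.28, adjusted p = 0.0329). Pdcd1, encoding the checkpoint receptor PD-1 (2.83 ± 0.48), Epha3 (3.59 ± 0.54) and Ier5l (2.93 ± 0.27) rose, and Dapl1 (−3.27 ± 0.37), Igfbp4 (−3.35 ± 0.49) and St8sia1 (−2.44 ± 0.27) fell. Under the inhibitor, against control, Gzmk (3.35 ± 0.48), Epha3 (3.00 ± 0.54), Fabp5 (2.71 ± 0.31) and Ier3 (2.69 ± 0.46) rose and Dapl1 (−3.26 ± 0.37), Igfbp4 (−2.79 ± 0.48), St8sia1 (−2.70 ± 0.28), Lef1 (−2.48 ± 0.28) and Satb1 (−2.16 ± 0.31) fell. Fabp5 in T-like cells stood at 0.00980 times its CPM in macrophage-like cells (median of the 6 Cre-positive libraries). Ctla4 (1.51 ± 0.27, adjusted p = 0.0515, vehicle minus control) and Ifng (1.91 ± 0.38, adjusted p = 0.0646, inhibitor minus control) did not pass.

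In the effector and regulatory list, 2 of 27 members rose and 0 fell (16 and 0 adjusted over the list alone, median 1.26, camera adjusted p = 9.64e-12, adjusted p = 0.0307 with an estimated correlation) for vehicle minus control. In the naive list, 0 of 10 members rose and 4 fell (0 and 9 adjusted over the list alone, median −1.87, camera adjusted p = 1.69e-12, adjusted p = 0.0307 with an estimated correlation). Inhibitor minus control gave medians of 1.18 (camera adjusted p = 1.17e-09, 1 member called and 17 adjusted over the list alone) and −1.86 (adjusted p = 5.60e-12, 4 called and 9 adjusted over the list alone), and adjusted p = 0.0463 for both with an estimated correlation. Inhibitor minus vehicle gave −0.14 (adjusted p = 0.135) and −0.02 (0.778), with Ctla4 at −0.61 ± 0.27 and Il17a at 1.30 ± 0.73. Of 12345 genes, edgeR called 42 up and 40 down for vehicle minus control, 36 up and 55 down for inhibitor minus control, and 0 for inhibitor minus vehicle (168 at an unadjusted p under 0.05, DESeq2 1). T-like clusters 10 and 18, led by Lef1, held 774, 611 and 345 cells in control mice, 151, 89 and 42 in vehicle and 56, 115 and 127 in inhibitor mice. Without them edgeR called 1 and 2 genes against control. A fit of the 2 groups compared called 1 and 12, and with doublets kept 782 and 840 were called. Counts were 19 and 22 with age and 127 and 227 with sex as covariate, 666 and 671 by DESeq2, 644 and 630 with the stricter cell filter and 227 and 194 with no low-count filter. Vehicle minus control called 0 genes without control mouse 1, 1 without control 2, 814 without control 3, 226 without vehicle 1, 1 without vehicle 2 and 4 without vehicle 3. Inhibitor minus control called 0, 9 and 1028 genes without control mice 1 to 3 and 0, 1 and 17 without inhibitor mice 1 to 3. Inhibitor minus vehicle called 1 list without vehicle 1.

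In monocyte-like cells the naming rule gave, among rises, Itgad, an integrin alpha chain gene next to Itgax (chromosome 7, 128154376 to 128223816), and Plcb4, a phospholipase (chromosome 2, 135659011 to 136014593). Itgad stood at 87.5 ± 42.4 CPM in vehicle and 4.09 ± 4.40 in control mice (4.90 ± 0.59, adjusted p = 0.00872), and Plcb4 changed by 4.01 ± 0.67, adjusted p = 0.0175. A predicted gene left out by the rule, 4931431B13Rik, rose by 6.64. The proteoglycan gene Vcan (1.69 ± 0.30) and the collagenase Mmp8 (1.58 ± 0.34) rose, and the B-cell genes Igkc (−4.10 ± 0.80) and Ebf1 (−2.51 ± 0.46), with Myo1e (−2.99 ± 0.54) and Kcnq5 (−2.64 ± 0.54), fell. Cluster 5, led by Chil3, held 177, 37 and 112 of the 361, 161 and 355 control, 517, 156 and 130 of the 671, 321 and 398 vehicle and 473, 189 and 117 of the 888, 400 and 362 inhibitor cells. Cluster 30, with Vcan among its leading genes, held 2, 4 and 11 control, 35, 37 and 9 vehicle and 51, 16 and 20 inhibitor cells. Of 10287 genes edgeR called 53 up and 119 down for vehicle minus control and 0 for inhibitor minus vehicle (173 at an unadjusted p under 0.05, DESeq2 0). Inhibitor minus control called 3 up, Itgad (5.22 ± 0.58), 9630028H03Rik (2.16) and 4931431B13Rik (45.85 against 0.258 CPM), the last pair named after their values were seen. With doublets kept vehicle minus control called 9 genes. Both contrasts against control called 302 and 22 with age and 372 and 18 with sex as covariate, 298 and 56 by DESeq2, 112 and 5 with the stricter filter, 97 and 7 in a fit of the 2 groups and 884 and 478 with no low-count filter. It called 47 without control mouse 1, 69 without control 3, 104 without vehicle 1 and 7 without vehicle 2, and inhibitor minus control called 0 without control 1, 5 without control 2 and 5 without inhibitor 1.

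NK-like cells showed the same pair, Itgad (3.24 ± 0.39, adjusted p = 0.00650) and Plcb4 (1.75 ± 0.14, adjusted p = 3.29e-04), for vehicle minus control. The sulfotransferase Sult2b1 (2.83 ± 0.37) and transferrin, Trf (1.45 ± 0.18), rose, and Gramd4 fell (−0.90 ± 0.14). For inhibitor minus control Itgad (3.58 ± 0.38), Fabp5 (3.46 ± 0.44) and Plcb4 (1.77 ± 0.14) rose. The other 3 of these 6 calls, also called in vehicle mice and named after their values were seen, were Plcb1 (3.96 and, in vehicle mice, 3.84), 4931431B13Rik (4.11 and 3.82) and 9630028H03Rik (64.9 and 45.5 CPM against 0 in control). Plcb1 (chromosome 2, 134786067 to 135475258) overlaps 9630028H03Rik upstream of Plcb4. Cluster 9, with 4931431B13Rik among its leading genes, held 44, 19 and 155 of the 463, 150 and 272 control, 118, 171 and 82 of the 307, 232 and 166 vehicle and 755, 109 and 87 of the 1090, 241 and 315 inhibitor NK-like cells. Against macrophage-like cells of the same Cre-positive libraries, the median CPM ratio in NK-like cells was 24.1 for Itgad, 11.8 for Plcb4 and 0.00838 for Fabp5. Of 9024 genes edgeR called 8 up and 1 down, 6 up, and 0 for inhibitor minus vehicle (229 at an unadjusted p under 0.05, DESeq2 0). Vehicle minus control called 37 genes without control mouse 3 and 26 without vehicle 1, and inhibitor minus control called 15 without inhibitor 1. In B-like cells Fabp5 rose in vehicle (4.57 ± 0.49) and inhibitor mice (5.64 ± 0.49) against control, and Plcb4 by 3.31 and 3.38. Gpnmb, with 0 CPM in control B-like cells, was also called (8.72 and 15.5 CPM), Plcb4 and Gpnmb being named after their values were seen. The median CPM ratio of B-like to macrophage-like cells was 0.00785 for Fabp5, 0.00565 for Gpnmb and 1.20 for Plcb4. Of 11660 genes edgeR called 3 and 6 up against control and 0 for inhibitor minus vehicle (285 at an unadjusted p under 0.05, DESeq2 0). Vehicle minus control called 1 gene without control mouse 1 and 0 without control 2, and inhibitor minus control 0 without control 2 and 3 without control 3 or inhibitor 2 or 3.

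**Figure D4:**
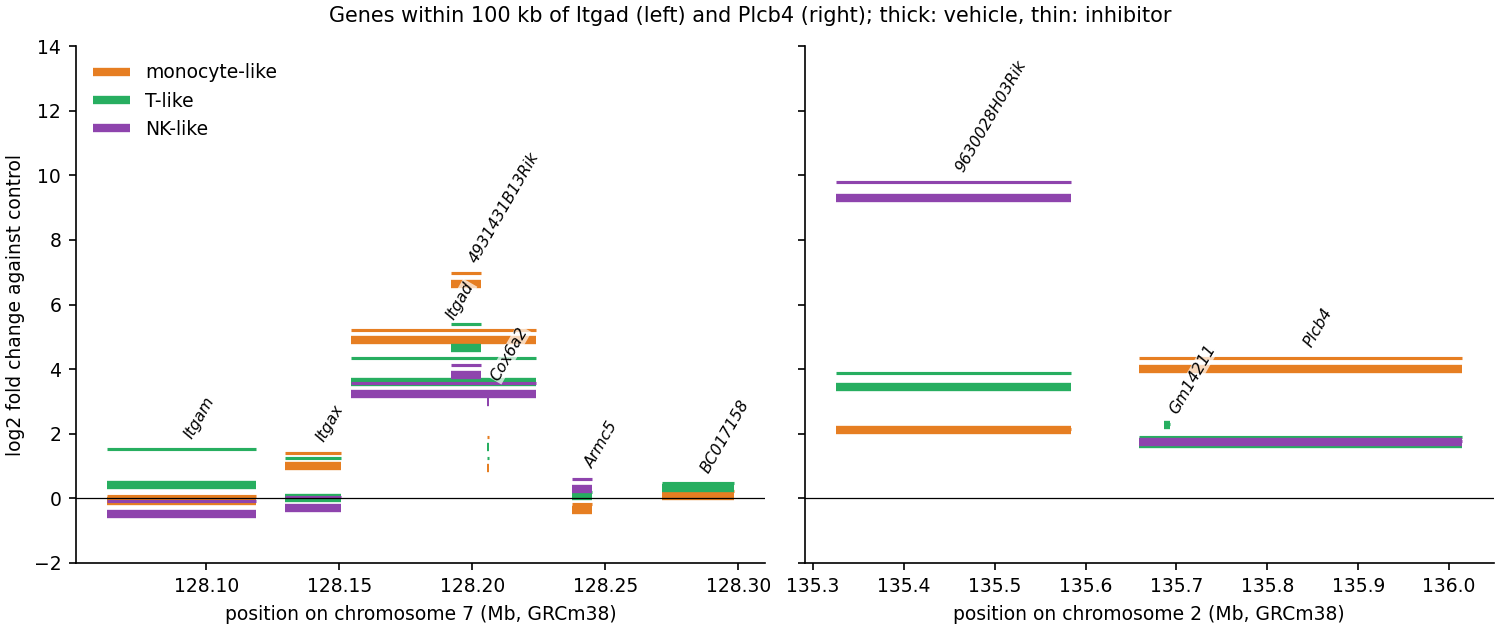
Log2 fold change against control of genes within 100 kb of Itgad and of Plcb4 at their genomic positions, in monocyte-like, T-like and NK-like cells. Thick lines are vehicle and thin lines inhibitor mice. Itgad lies at 4.90 and 5.22 in monocyte-like cells.

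cDC-like cells of vehicle mice held more transcript of Fscn1, a marker of migrating dendritic cells (4.65 ± 0.96, adjusted p = 0.0447), Mreg (4.26 ± 0.91), the amino acid oxidase Il4i1 (3.38 ± 0.51) and Fabp5 (3.21 ± 0.66, at a median of 0.0235 times the CPM in macrophage-like cells of Cre-positive libraries) than those of control mice. They held less of Lef1 (−5.91 ± 0.59), Sidt1 (−4.05 ± 0.55) and the complement genes C1qb (−3.32 ± 0.58) and C1qa (−3.20 ± 0.59). Lef1 and Sidt1 are also leading genes of T-like clusters and C1qa of macrophage-like clusters, and the cDC-like cluster had a median doublet score of 0.0923 and 11791 UMIs. Of 7299 genes edgeR called 22 up and 44 down in this contrast. Inhibitor minus control called Hpgds up (3.07 ± 0.45) and Lef1 down (−3.43 ± 0.44), and inhibitor minus vehicle 0 (325 at an unadjusted p under 0.05, DESeq2 2). Cells per library numbered 20 to 186. Vehicle minus control called 32 genes without control mouse 2, 31 without control 3, 16 without vehicle 1, 1 without vehicle 2, 17 without vehicle 3 and 18 with doublets kept. Inhibitor minus control called 6 without control 1, 0 without inhibitor 1 and 1 without inhibitor 2, and inhibitor minus vehicle called 1 without vehicle 1.

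Neutrophil-like cells showed shifts of whole lists and no called gene. Against control, vehicle mice had higher activation genes (median 0.43, camera adjusted p = 7.41e-05, adjusted p = 0.273 with an estimated correlation) and maturity and granule genes (median 0.25, camera adjusted p = 0.0200, adjusted p = 0.303 with an estimated correlation), with Cxcl2, a neutrophil chemokine, at 1.20 ± 0.40, adjusted p = 0.279 and Retnlg at 1.22 ± 0.39, adjusted p = 0.274. Inhibitor minus vehicle gave a lower activation list (median −0.24, camera adjusted p = 0.00592, adjusted p = 0.525 with an estimated correlation) and no call for maturity (adjusted p = 0.963). Inhibitor minus control gave activation (median 0.27, camera adjusted p = 0.00900, adjusted p = 0.298 with an estimated correlation) and maturity (median 0.06, camera adjusted p = 0.0179, adjusted p = 0.298 with an estimated correlation). Of 14 and 12 members 0 were called, over all genes and over the list alone. Of 6173 genes edgeR called 0 in the 3 contrasts (771, 111 and 515 at an unadjusted p under 0.05, in the order vehicle minus control, inhibitor minus vehicle and inhibitor minus control), and DESeq2 called 85, 0 and 11. Of the 2 lists, vehicle minus control called 1 without control mouse 3 or vehicle 1, inhibitor minus vehicle 0 without vehicle 2 or inhibitor 3 and 2 without vehicle 3, and inhibitor minus control 1 without control 1 or inhibitor 2 and 0 without inhibitor 1. With age as covariate or doublets kept both contrasts against control called 1. EdgeR called 2 genes for vehicle minus control without control 2 and 1 for inhibitor minus control without inhibitor 3.

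Fibroblast-like and endothelial-like cells were tested after seeing that some libraries held fewer than 20 of them (5 to 463 and 11 to 142 cells). In fibroblast-like cells the vehicle against control matrix list was called higher (median 0.04, camera adjusted p = 0.0321, adjusted p = 0.516 with an estimated correlation), the resting list higher (median 0.05, camera adjusted p = 0.0155, adjusted p = 0.516 with an estimated correlation) and dissociation genes lower (median −0.42, camera adjusted p = 0.00144, adjusted p = 0.516 with an estimated correlation). Comp, a matrix protein (2.05 ± 0.72), and Lox, a collagen crosslinker (1.14 ± 0.45), did not pass. Myofibroblast (adjusted p = 0.695) and interferon genes (0.874) were not called, 0 list members were called, and no list was called for the other contrasts. Of 6916 genes edgeR called Nfasc in vehicle and inhibitor mice over control (27.9, 34.2 and 0.204 CPM), named after seeing its values. Inhibitor minus vehicle called 0 (187 at an unadjusted p under 0.05, DESeq2 2). Vehicle minus control called 0 lists without control mouse 1 and 1 without control 3, where 3 were called with all mice, and 1 with doublets kept or the stricter cell filter. Inhibitor minus vehicle called 1 list without vehicle 1 or inhibitor 3 and 2 without vehicle 2 or inhibitor 1, and 7 genes without inhibitor 1. Inhibitor minus control called 2 lists without control 2 and 1 without control 3 or inhibitor 1. Vehicle minus control called 0 genes without control 2, control 3, vehicle 1 or vehicle 3, and inhibitor minus control 0 without control 2, control 3 or inhibitor 1.

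Endothelial activation genes were higher in vehicle than control mice (median 0.81, camera adjusted p = 2.17e-04, adjusted p = 0.0388 with an estimated correlation) and lower in inhibitor than vehicle mice (median −0.87, adjusted p = 0.00172, adjusted p = 0.0539 with an estimated correlation). Vwf, von Willebrand factor, stood at 0.99 ± 0.35 and −0.99 ± 0.37 and the adhesion receptor Vcam1 at 1.03 ± 0.43 for vehicle minus control, none past the test. Inhibitor minus control was not called (adjusted p = 0.785). Of 11 members 0 were called over all genes and over the list alone, and of 4765 genes edgeR called 0 in the 3 contrasts (161, 102 and 162 at an unadjusted p under 0.05) and DESeq2 0. With doublets kept the medians were 0.33 for vehicle minus control, not called, and 0.30 for inhibitor minus vehicle. Inhibitor minus vehicle was not called without vehicle mouse 1 or 3 or inhibitor mouse 1 or 2, with no low-count filter, with the stricter cell filter or at resolution 2. Inhibitor minus control called 2 genes without control mouse 3.

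The makeup of the immune cells varied widely between mice. Neutrophil-like cells made up 2.39 ± 1.25% of control, 7.71 ± 4.43% of vehicle and 6.01 ± 2.79% of inhibitor immune-like cells (mean ± SD, n = 3 mice), and cDC-like cells 2.45 ± 2.30% of control, 0.775 ± 0.372% of vehicle and 0.777 ± 0.333% of inhibitor. Mast and basophil-like cells made up 0.719%, 2.13% and 1.79%, macrophage-like cells 10.1 ± 7.5% of control, 9.79 ± 3.51% of vehicle and 14.3 ± 5.40% of inhibitor and monocyte-like cells 7.27 ± 3.03% of control, 11 ± 3.12% of vehicle and 11.9 ± 6.71% of inhibitor. Shares of B-like cells were 43.5%, 35.8% and 31.7%, of T-like cells 24.3%, 25.6% and 19.8%, of NK-like cells 7.20%, 5.60% and 11.9% and of ILC2-like cells 2.03%, 1.64% and 1.85%, and inhibitor mouse 1 had an NK-like share of 24.0%. No class passed an exact permutation test over the 3 groups (lowest adjusted p = 0.643). With both Cre-positive groups set against control, chosen after seeing the data, exact p was 0.0476 for cDC (adjusted 0.25, 4 of 6 below all controls) and 0.0833 for neutrophil-like (4 of 6 above all controls) and mast-like cells (5 of 6 above). Non-immune cells were fibroblast-like (45.9%, 42.4% and 36.6% in control, vehicle and inhibitor mice), endothelial-like (42.5%, 45.8% and 50.7%) or cardiomyocyte-like (11.6%, 11.9% and 12.7%). The CD45 sort sets the immune share, and it can set the shares of classes within it.

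**Figure D5:**
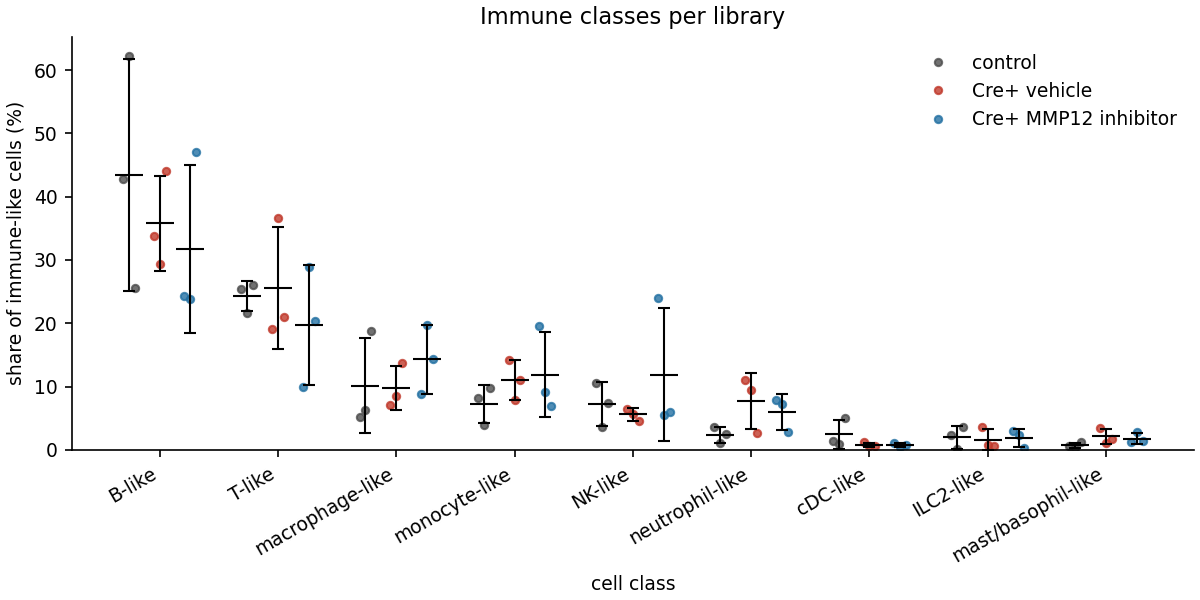
Share of 9 immune classes among immune-like cells in percent, by group. Points are libraries and bars the mean ± SD of 3 mice. Neutrophil-like cells average 2.39% in control and 7.71% in vehicle mice.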

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

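Cluster 22 had 6 markers of its best class and 5 of monocytes, stayed unnamed and was in no comparison. It held a mean of 1.57% of analysed cells of the 6 Cre-positive libraries (control 0.448 ± 0.214%). Its leading genes were Il1r2, Csf3r, Olr1, Adgre4 and Ace, from 514 cells with a median of 11608.5 UMIs and a median doublet score of 0.0952. The share was 1.43 ± 0.577% in vehicle and 1.71 ± 0.638% in inhibitor mice, above all controls in 6 of 6 Cre-positive libraries (exact permutation p = 0.0238, not adjusted over the 4 unnamed clusters, a grouping chosen after seeing the data). No explanation for it was tested. Groups of 3 libraries were not tested for outlying samples.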

How the results depend on the processing

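Called counts in macrophage-like cells kept their size within 1.5 times in most settings, and the cause was not tested where a value moved, except where fewer cells or libraries were used. Of 477 counts of called genes under alternatives 336 stayed within 1.5 times and 141 moved, and of 240 counts of called lists 201 stayed and 39 moved. Of 2210 single list values 1804 were the same, 89 lost and 102 gained a call, 205 moved and 10 reversed. Of 7058 values of named genes 6343 were the same, 533 lost and 123 gained a call, 45 moved and 14 reversed. Differences in class shares kept their sign or moved by under 1 SD in 348 of 348 alternatives, of which 27 are edgeR tests on cell numbers, judged by sign, and UMI shares in 238 of 243. Of the 564 without those tests, 65 had the opposite sign or were at 0, and 5 of those moved by at least 1 SD. The rule of 1 SD replaced one on any change of sign after those values were seen. Vehicle minus control and inhibitor minus control shared 913 calls at an adjusted p under 0.01. No paired analysis was possible because the labels carry no replicate numbers and the sources used here do not say which mice share a litter or day, and the numbers used here follow the order of the sample list. The age labels, used as covariate, were 43, 39 and 39 in control mice 1 to 3, 43, 43 and 40 in vehicle and 43, 43 and 39 in inhibitor mice. Mice numbered 1 stood together in fibroblast-like shares of non-immune cells, 83.3%, 81.7% and 57.0% in control, vehicle and inhibitor mice against 20.4% to 29.9% in the other 6. The filters left out 113 to 265 barcodes in 5 females of age label 43. They cut 393 to 583 in 3 males and 1 female of 39 or 40. Depth limits the low-count genes, and macrophage-like cells of Cre-positive mice had fewer UMIs. Settings without the Gpnmb-led or Lef1-led clusters, of 2000 UMIs and with the 6 against 3 grouping were chosen after seeing the data.

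With the DESeq2 Wald test, genes called were for vehicle minus control B-like 15, monocyte-like 298, NK-like 40, neutrophil-like 85, T-like 666, cDC-like 112 and fibroblast-like 6, and for inhibitor minus vehicle T-like 1, cDC-like 2 and fibroblast-like 2, and for inhibitor minus control B-like 42, monocyte-like 56, NK-like 22, neutrophil-like 11, T-like 671, cDC-like 9 and fibroblast-like 15. With a 2-fold minimum, genes called were for vehicle minus control macrophage-like 1134, and for inhibitor minus control macrophage-like 782. With age as covariate, genes called were for vehicle minus control monocyte-like 302, neutrophil-like 1, T-like 19 and fibroblast-like 0, and for inhibitor minus control monocyte-like 22, T-like 22, cDC-like 5 and fibroblast-like 0. Lists called with age as covariate were for vehicle minus control neutrophil-like 1, and for inhibitor minus control neutrophil-like 1 and fibroblast-like 1. With cells of at least 2000 UMIs, genes called were for inhibitor minus control macrophage-like 1297. With clustering resolution 2, genes called were for vehicle minus control NK-like 5, and for inhibitor minus control cDC-like 10. Lists called with clustering resolution 2 were for inhibitor minus vehicle endothelial-like 0. With doublets kept, genes called were for vehicle minus control monocyte-like 9, T-like 782, cDC-like 18 and fibroblast-like 0, and for inhibitor minus control monocyte-like 5, neutrophil-like 1, T-like 840, cDC-like 4 and fibroblast-like 0. Lists called with doublets kept were for vehicle minus control neutrophil-like 1, fibroblast-like 1 and endothelial-like 0, and for inhibitor minus vehicle macrophage-like 5, and for inhibitor minus control neutrophil-like 1 and endothelial-like 1. List medians with doublets kept were amino acid and ATF4 inhibitor minus vehicle 0.0366, T-cell marker inhibitor minus vehicle −0.27, endothelial activation vehicle minus control 0.33, endothelial activation inhibitor minus vehicle 0.30. With no low-count filter, genes called were for vehicle minus control B-like 168, monocyte-like 884, NK-like 425, neutrophil-like 269, T-like 227, cDC-like 457, fibroblast-like 141 and endothelial-like 39, and for inhibitor minus vehicle B-like 79, macrophage-like 104, monocyte-like 56, NK-like 54, neutrophil-like 30, cDC-like 76, fibroblast-like 120 and endothelial-like 20, and for inhibitor minus control B-like 239, monocyte-like 478, NK-like 279, neutrophil-like 93, T-like 194, cDC-like 197, fibroblast-like 109 and endothelial-like 29. Lists called with no low-count filter were for inhibitor minus vehicle T-like 1 and endothelial-like 0, and for inhibitor minus control fibroblast-like 2 and endothelial-like 1. With a fit of the 2 groups compared, genes called were for vehicle minus control monocyte-like 97, neutrophil-like 1, T-like 1, fibroblast-like 0 and endothelial-like 1, and for inhibitor minus control monocyte-like 7, T-like 12, cDC-like 0 and fibroblast-like 0. With sex as covariate, genes called were for vehicle minus control monocyte-like 372, T-like 127 and fibroblast-like 0, and for inhibitor minus control monocyte-like 18, T-like 227, cDC-like 1 and fibroblast-like 4. With the stricter cell filter, genes called were for vehicle minus control monocyte-like 112, T-like 644 and fibroblast-like 0, and for inhibitor minus control B-like 3, monocyte-like 5, T-like 630, fibroblast-like 0 and endothelial-like 1. Lists called with the stricter cell filter were for vehicle minus control fibroblast-like 1, and for inhibitor minus vehicle endothelial-like 0, and for inhibitor minus control fibroblast-like 1.

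Without the Gpnmb-led cluster edgeR called 0 genes for vehicle minus control (749 at an unadjusted p under 0.05) and 0 for inhibitor minus control (574). List medians without it were sterol synthesis vehicle minus control −0.0704, fibrogenic inhibitor minus vehicle 0.0279, cell cycle inhibitor minus vehicle −0.0758, sterol synthesis inhibitor minus control 0.11. Genes that reversed without it were, for vehicle minus control, Timp2 −0.058, Selenop −0.30, Tnfsf12 −0.43, Fdps −0.12, Ctsb −0.0171, Atf5 −0.15, Gdf15 −0.0127. For inhibitor minus control they were Mmp12 −0.0279, Timp2 −0.23, Selenop −0.38, Lyz2 −0.11, Tnfsf12 −0.0957, Msmo1 −0.16, Atf5 −0.54. Without the Lef1-led clusters edgeR called 1 gene in T-like cells for vehicle minus control and 2 for inhibitor minus control. Not thinned, share differences in percentage points were Itgax inhibitor minus control −1.13, Arg1 inhibitor minus vehicle −0.503 and Arg1 inhibitor minus control −0.00812. Thinned to 1000 UMIs they were Itgax vehicle minus control 0.509 and Arg1 inhibitor minus vehicle −0.363.

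Leaving out each replicate in turn, genes called ranged for vehicle minus control B-like 0 to 2, NK-like 6 to 37, T-like 0 to 814, cDC-like 1 to 69, fibroblast-like 0 to 1, monocyte-like 7 to 223 and neutrophil-like 0 to 2. They ranged for inhibitor minus vehicle cDC-like 0 to 1 and fibroblast-like 0 to 7, and for inhibitor minus control B-like 0 to 9, NK-like 5 to 15, T-like 0 to 1028, cDC-like 0 to 6, endothelial-like 0 to 2, fibroblast-like 0 to 1, macrophage-like 1357 to 1902, monocyte-like 0 to 5 and neutrophil-like 0 to 1. Lists called ranged for vehicle minus control fibroblast-like 0 to 3 and neutrophil-like 1 to 2, and for inhibitor minus vehicle T-like 0 to 1, endothelial-like 0 to 1, fibroblast-like 0 to 2 and neutrophil-like 0 to 2, and for inhibitor minus control fibroblast-like 0 to 2 and neutrophil-like 0 to 2. List medians ranged for MHC class I inhibitor minus vehicle −0.16 to 0.41 and monocyte-derived inhibitor minus vehicle −0.69 to 0.0934.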

Other observations

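Itgad and Plcb4, named after their values were seen, were higher in Cre-positive hearts across immune classes. In NK-like cells Itgad stood at 24.0 ± 12.1 CPM in control, 222 ± 57.9 in vehicle and 277 ± 113 in inhibitor mice, and Plcb4 at 69.6 ± 9.51, 237 ± 21.1 and 239 ± 13.5. Itgad was at least 2-fold higher with an unadjusted p under 0.05 in both Cre-positive groups in 6 of 6 classes, and Plcb4 in 7 of 7. The neighbours 4931431B13Rik and Cox6a2 overlap Itgad on the opposite strand, and without known strand use their reads cannot be told apart from those of Itgad.

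For the macrophage-like calls of vehicle minus control, the length trend and other-cluster tests were chosen after seeing the result. Of the 2803 called genes, 66.9% were called with the same sign among cells of at least 2000 UMIs and 59.6% with the trend on transcript length removed, which argues against low-UMI barcodes or the length trend as the whole cause. The 10 leading genes of the Gpnmb-led cluster had a median B-like share of 0.0136 times the macrophage-like share. Choosing leading genes favours this, so free RNA stays open. Without the Gpnmb-led cluster edgeR called 0 of the 2803 genes (749 genes at an unadjusted p under 0.05, 88.3% of the called genes with the same sign), but that cluster held 0, 0 and 4 cells of control mice 1 to 3, so leaving it out takes cells from the Cre-positive groups and decides nothing (medians then 0.19 against 0.96 for risers and −0.30 against −0.77 for fallers). For oxidative phosphorylation the median was 0.71 with the trend removed and 1.09 with it, and a part from the trend cannot be told apart from a change of these genes.

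For the T-like lists the test was chosen before its result was seen. Without the Lef1-led clusters the effector median was 0.30, against 1.26 with them, so the lists may reflect the share of these clusters. Whether that share follows from the genotype or from the sort of each heart was not tested.

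For Itgad and Plcb4, all 3 tests were chosen after seeing the result. Itgad CPM in NK-like cells was 24.1 times that in macrophage-like cells of Cre-positive libraries, which argues against free RNA of macrophage-like cells. Outside macrophage-like cells, 5.56% of tests of non-overlapping genes within 100 kb of Itgad were higher (1 of 18 tests of 4 genes), against 0.958% of other gene and class tests. The value was 100% around Plcb4, but its 3 tests are those of 1 gene, 9630028H03Rik, in monocyte-, T- and NK-like cells of the same mice (within 500 kb, 4 of 10 tests of 3 genes, with Plcb1 in NK-like cells, and 2 of 114 around Itgad). With so few genes or tests an altered region around either cannot be told apart from other causes, and reads over the ends of the CD11c Cre transgene would test it.

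NK-cell markers in macrophage-like cells, inhibitor minus vehicle, had a median of 1.76 without inhibitor mouse 1 and 2.64 with it.

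Other splits of the same libraries were counted for each set of called genes, and 10 splits are too few for a share under 0.05. Real counts, with the highest other split in brackets, were for vehicle minus control macrophage-like 2803 (0), monocyte-like 172 (1), T-like 82 (0), cDC-like 66 (0), NK-like 9 (1), B-like 3 (1), fibroblast-like 1 (1), endothelial-like 0 (4), neutrophil-like 0 (34). For inhibitor minus control they were macrophage-like 2228 (0), T-like 91 (0), B-like 6 (14), NK-like 6 (0), monocyte-like 3 (1), cDC-like 2 (2), fibroblast-like 1 (0), endothelial-like 0 (2), neutrophil-like 0 (0). For inhibitor minus vehicle they were 0 in the 9 classes, with 96 in fibroblast-like, 1 in cDC-like and 0 in the other 7 classes as the highest. The numbers of splits with as many calls, the real one included, were 1, 2, 10 for vehicle minus control, 1, 2, 3, 10 for inhibitor minus control and 10 for inhibitor minus vehicle. Splits with 34 neutrophil-like and 14 B-like calls set 3 females of age label 43 against 2 males and 1 female of 39 or 40. That with 96 fibroblast-like calls sets vehicle 1 and 2 and inhibitor 1 against the rest. Counts far above the real one point to sample structure, and its cause was not tested. With both Cre-positive groups against control, chosen after seeing the data, real counts were macrophage-like 3431 (5), T-like 762 (8), monocyte-like 180 (98), cDC-like 25 (16), NK-like 10 (35), fibroblast-like 6 (46), neutrophil-like 6 (27), B-like 3 (13), endothelial-like 0 (6). As many calls came from 1 of 84 splits for macrophage-, T-, monocyte- and cDC-like cells (adjusted over 9 classes 0.0268), 2 for NK-like (0.0429), 3 for neutrophil-like and 4 for fibroblast- and B-like (0.0536) and 84 for endothelial-like cells (1). Splits with several times the real count in B-, fibroblast-, neutrophil- and NK-like cells point to a structure of the samples, and the highest in B- and neutrophil-like cells holds control 2, control 3 and vehicle 3, all of age label 39 or 40. Age labels are unbalanced, with 1 of 3 control and 4 of 6 Cre-positive mice at 43. Of the 30 splits that keep the real number of mice at 43, 1 gave as many calls in these classes (adjusted 0.0429) except NK-like (2, 0.075) and endothelial-like cells (30). Of the 45 that keep the number of males, 1 did (adjusted 0.0286) except for fibroblast-like (2, 0.05) and endothelial-like cells (45). These 3 overlapping counts gave adjusted shares under 0.05 for macrophage-, T-, monocyte- and cDC-like cells.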
